A study of Mus musculus with 4 samples.

How the data were processed

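RNA was sequenced from leukaemic spleen cells of mice carrying MLL-AF9 acute myeloid leukaemia, a transplanted leukaemia driven by the MLL-AF9 fusion gene. Per the series' design text, CD45.2 donor leukaemia cells were given to irradiated secondary recipients (320 rads), which then received PBS or the FTO inhibitor CS1 at 5 mg/kg, by intraperitoneal injection on alternate days over 20 days. Spleen cells were enriched for CD45.2 with antibody and beads, and poly(A) RNA was selected, per the same text. There were 4 libraries, PBS replicates 1 and 2 and CS1 replicates 1 and 2. Groups were taken from the sample titles. The treatment field of CS1 replicate 2 reads CS2, while its title, its description, the treatment protocol and the design text give CS1; it was grouped as CS1, and leaving it out was one of the alternatives fixed before the data were examined.

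The submitters' processing notes name STAR, RSEM and the genome build mm10, without versions, and the roles of the tools and the annotation are not given in the sources used here. The deposited table lists 24497 features in 4 columns, and its values were taken as TPM (the usual length-normalized transcript share) made by the authors. The unit is stated neither in the header nor in the labels; it was inferred from column sums between 977973 and 986345, from values with decimals, and from the mention of RSEM, which writes TPM. The lowest listed value is 0.01, which stands where a 0 would be expected, and 7674 features are listed at 0.01 in all 4 libraries. TPM keeps no read depth, so the depth per library is unknown and no counting interval is given. Without counts it could not be tested whether replicates of a group differed by more than sampling noise. TPM is also a share of the total, so a fall in an abundant transcript raises the values of all others.

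Values were transformed to log2(TPM + 1), and features with at least 1 TPM in at least 2 of the 4 libraries were tested, which left 11866. CS1 was compared with PBS in limma 3.58.1 (R 4.3.3) with the variance trend on, as a two-sided test with Benjamini-Hochberg adjustment over all tested features and a call at an adjusted p under 0.05. All gene-level adjusted p-values are from this test. Log2 fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. With 2 libraries against 2, an exact permutation test of one gene cannot give a two-sided p under 0.333, so each gene's test leans on the spread shared across genes. The design had been written for counts or normalized values, and the branch for normalized values was used.

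A set of 34 gene lists was written before the data were examined: m6A machinery, FTO-linked targets, immune checkpoints, the MLL leukaemia programme, MYC and nucleolar targets, ribosomal proteins, DNA replication, mitosis, p53 targets, intrinsic apoptosis, promyelocyte granule genes, late neutrophil genes, monocyte and macrophage genes, dendritic cell genes, MHC class II, MHC class I, T cell, cytotoxic and NK cell, B cell, plasma cell, erythroid, megakaryocyte and platelet, mast cell with basophil and eosinophil, stroma and endothelium, interferon response, NF-kB and inflammation, immediate early genes, heat shock and unfolded protein response, glycolysis and hypoxia, the respiratory chain, cholesterol synthesis, pyrimidine and purine synthesis, lysosome and autophagy, and complement with efferocytosis. Each list with at least 5 tested members was tested with limma's camera at an inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 34 lists. Camera with an estimated correlation and fry were run as alternatives. The FTO-linked list was drawn from published work that may rest partly on these samples.

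Named genes followed a rule fixed before the data were examined. Its first part takes the 10 highest and 10 lowest log2 fold changes among called genes whose groups do not overlap and whose higher mean is at least 5 TPM, without predicted symbols, ribosomal genes and immunoglobulin or T cell receptor segments. Its second part takes the 3 members with the smallest p, in the direction of the list, of each called list and the 2 with the smallest p of each other list. The third part names Fto, Alkbh5, Myc, Cebpa, Asb2, Rara, Lilrb4a, Hoxa9, Meis1, Cd274, Mki67, Cdkn1a, Dhodh and Ptprc. The first part gave mostly short noncoding RNAs, so it was repeated over protein-coding genes not listed at 0.01 in a whole group, a repeat chosen after seeing the data. Other genes named outside the rule are said to be so. Some genes that the rule takes are not reported here.

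Coordinates and exons are from GENCODE M21 on GRCm38, the assembly of mm10, and 11548 of the tested features matched it by symbol. The named genes number 118, and exons of 21 of them overlap an exon of another tested feature; whether counting used the strand is not given in the sources used here, so their values are uncertain to that extent. Among them are Cdc20, Rps18, Rpl12, Nop56, Tk1, Cox6c, Ndufa2, Egfl7 and Sult1a1, which share at most 250 bases with a gene on the opposite strand, and Hoxa9 and Cd74, which share 85 and 12 bases with a microRNA. The alternatives were a rescaling by the trimmed mean of M values, quantile normalization, the variance trend off, no filter, a filter of 5 TPM, pseudocounts of 0.1 and 5, the replicate number as a block, each library left out in turn, and thresholds of an adjusted p under 0.1 or a log2 fold change of at least 1. Leaving out the short noncoding features was added after seeing the data. Values were simulated for the 11866 tested features, with 200 of them changed. The gene test recovered 40%, 74%, 96% and 100% of changes of 0.25, 0.5, 1 and 2 on the log2 scale. It called 15 of 11666 unchanged features. In the data 67.0% of features were called, far more than were changed in the simulation, so these rates need not hold there. On simulated values camera called 0 of 33 random lists. A simulated list shifted by 0.5 had an adjusted p of 0.0636 in camera with an estimated correlation. The simulated features varied independently, unlike the data, so these list results need not hold for lists of genes that vary together. Figures were drawn with matplotlib 3.10.9.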

Results

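Gene expression was measured by poly(A) RNA sequencing in CD45.2-enriched spleen cells of mice with MLL-AF9 acute myeloid leukaemia, an aggressive leukaemia model in which the donor cells carry the MLL-AF9 fusion. The mice had received CS1, described in the labels as an inhibitor of the RNA demethylase FTO, at 5 mg/kg, or PBS as the control, over 20 days. Each group had 2 libraries. The treatment field of CS1 replicate 2 names CS2, against CS1 in its title and in the other descriptions, and the library was kept in the CS1 group. The deposited values, taken as TPM, summed to 986084 and 986345 in PBS and to 977973 and 978426 in CS1, and the read depth behind them is unknown. At least 1 TPM was reached by 11459 and 11489 features in PBS and by 11813 and 11812 in CS1. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

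The comparison asked how the transcriptome of these CD45.2-enriched cells differed between treatment with the FTO inhibitor and PBS. The labels name no leukaemia clones, so for every difference below, different clones in the groups cannot be told apart from the treatment. Genes of promyelocyte granules, of the MLL leukaemia programme, of mitosis and of the ribosome were higher in CS1, while interferon-response, inflammatory, heat shock and glycolysis genes were lower. Each of these list calls was lost with an estimated correlation (adjusted p = 0.449 to 0.46), and those of heat shock and glycolysis also after quantile normalization. In simulation, camera with an estimated correlation also missed a list shifted by 0.5 (adjusted p = 0.0636, against 6.92e-89 at the fixed correlation). A loss in that setting alone therefore does not show that a list is unchanged. The simulated features varied independently and nearly all were unchanged, unlike these data, so the simulation cannot tell why these calls were lost. Elane, which encodes neutrophil elastase, rose from 425 ± 2.34 TPM in PBS to 2512 ± 30.3 TPM in CS1 (SD, n = 2 each), a ratio of 5.91. Lyz2, the lysozyme of monocytes and granulocytes and an abundant transcript in these cells, fell from 13192 ± 90.5 to 6207 ± 20.5 TPM, or from 1.33% and 1.34% of the total to 0.633% and 0.636%. Elf4, a transcription factor of the ETS family, fell from 165 ± 3.87 to 8.88 ± 0.134 TPM. Of 11866 features tested with limma, 7949 (67.0%) differed at an adjusted p under 0.05, with 4194 higher and 3755 lower in CS1, and 886 of these changed by at least 1 on the log2 scale (596 higher, 290 lower). Many differences were small, since 4597 of the called features changed by less than 0.5. The groups did not overlap for 84.4% of features, against 33.3% by chance. The median log2 fold change over all tested features was 0.04. The majority direction depended on the scaling, with 3633 higher and 4328 lower after rescaling by the trimmed mean of M values. Quantile normalization gave 3844 higher and 3990 lower.

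Replicates lay close together. Pearson's r across the tested features was 0.993 between the PBS libraries and 0.991 between the CS1 libraries, and 0.958 for each of the 4 pairs across groups; features are not independent replicates. The median absolute log2 difference was 0.06 within either group, against 0.31 to 0.32 across groups. For 1788 features of at least 100 TPM on average it was 0.03 within groups and 0.29 to 0.30 across them.

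Promyelocyte granule genes made up the list with the largest median rise. Of its 16 tested members 13 rose and 3 fell, with a median log2 fold change of 1.35 (camera adjusted p = 0.000403, and adjusted p = 0.449 with an estimated correlation). Besides Elane (log2 fold change 2.56 ± 0.02, SE, adjusted p = 2.73e-07), Mpo, the myeloperoxidase of azurophil granules, rose from 161 ± 2.65 to 813 ± 11.6 TPM. Ms4a3, a marker of granulocyte-monocyte progenitors, rose from 87.5 ± 0.0495 to 391 ± 3.30 TPM. The members that fell were Ctsc, a protease that activates granule proteases (log2 fold change -1.56), the chaperone Calr and the granule proteoglycan Srgn, named after their values were seen. Late neutrophil genes as a list did not pass, with 19 of 31 higher and 10 lower (median 0.49, adjusted p = 0.069). That list passed in some alternatives, such as rescaling by the trimmed mean of M values (camera adjusted p = 0.0279, range 0.0279 to 0.449 across camera's alternatives). Within it Camp, the cathelicidin precursor, rose from 309 ± 2.40 to 1676 ± 14.2 TPM and Ngp, another protein of secondary granules, from 736 ± 15.9 to 3347 ± 31.8 TPM. Outside the naming rule, S100a8 and S100a9 rose to 5559 ± 204 and 7154 ± 195 TPM from 1795 ± 57.2 and 1983 ± 22.8 TPM, while Mmp8, Ltf and Csf3r fell, with log2 fold changes of -1.05, -0.65 and -0.87.

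Genes of the MLL leukaemia programme, which holds HOXA-cluster genes and stem and progenitor regulators, rose as a list, with 19 of 22 members higher and 1 lower (median 0.69, camera adjusted p = 7.00e-06, and adjusted p = 0.449 with an estimated correlation). Hoxa9 rose from 67.8 ± 2.06 to 159 ± 2.24 TPM (log2 fold change 1.22 ± 0.03, adjusted p = 4.47e-06). Myb, a transcription factor of haematopoietic progenitors, rose from 89.5 ± 0.0849 to 214 ± 1.06 TPM, the receptor kinase gene Flt3 from 188 ± 2.15 to 377 ± 1.13 TPM, and Meis1, a HOXA9 cofactor, from 25.9 ± 0.983 to 36.4 ± 0.587 TPM. The member that fell was Cd34, a progenitor surface marker (log2 fold change -0.59), named after its value was seen. Mitosis genes rose in 43 of 50 cases and fell in 1 (median 0.49, camera adjusted p = 2.28e-09, and adjusted p = 0.449 with an estimated correlation). Among them Ube2c and Cdc20, an enzyme and an activator of the anaphase-promoting complex, had log2 fold changes of 1.11 and 0.94, and the condensin gene Smc4 one of 1.08. Mki67, the Ki-67 proliferation marker, went from 147 ± 2.54 to 165 ± 1.26 TPM (log2 fold change 0.17, adjusted p = 0.00203). DNA replication genes did not pass as a list, with 15 of 50 higher and 12 lower, or 10 and 9 adjusted over the list alone (median 0.05, adjusted p = 0.725). In that list Tk1 was higher and Mcm6 lower, with log2 fold changes of 0.63 and -0.50.

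Ribosomal protein genes rose in 43 of 46 cases and fell in 0, with 44 higher adjusted over the list alone (median 0.31, camera adjusted p = 8.96e-12, and adjusted p = 0.46 with an estimated correlation). Rpl14, Rps18 and Rpl12 had log2 fold changes of 0.60, 0.46 and 0.55. MYC and nucleolar targets did not pass as a list, with 31 of 67 higher and 12 lower, or 30 and 12 adjusted over the list alone (median 0.11, adjusted p = 0.148). The ribosome biogenesis genes Ppan and Nop56 rose by 0.66 and 0.51. Respiratory chain genes were higher in 23 of 44 cases and lower in 4 (median 0.17, camera adjusted p = 0.0171, and adjusted p = 0.449 with an estimated correlation), with log2 fold changes of 0.45 for Ndufv2, 0.36 for Cox6c and 0.43 for Ndufa2. This call was lost after rescaling by the trimmed mean of M values (adjusted p = 0.0843) and with the variance trend off (0.0513), over a range of 1.70e-07 to 0.449 across camera's alternatives. Immediate early genes, which respond within minutes to stimulation, rose in 18 of 24 cases and fell in 2 (median 0.38, camera adjusted p = 0.000403, and adjusted p = 0.449 with an estimated correlation). Fosb rose from 172 ± 1.27 to 379 ± 2.76 TPM, and Klf2 and Jund had log2 fold changes of 0.70 and 0.75.

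MHC class II genes, which encode the antigen-presenting molecules and their partners, rose in 8 of 11 cases and fell in 1 (median 0.53, camera adjusted p = 0.0173, and adjusted p = 0.449 with an estimated correlation). Cd74, the invariant chain, rose from 618 ± 5.06 to 989 ± 0.891 TPM, and H2-Aa and H2-Ab1 had log2 fold changes of 0.72 and 0.55. Ctss, the cathepsin that cleaves the invariant chain, was the member that fell (log2 fold change -0.84), named after its value was seen. The call was lost with the variance trend off (adjusted p = 0.0513, range 0.00965 to 0.449 across camera's alternatives). MHC class I genes were higher in 5 of 23 cases and lower in 12 (median -0.26, adjusted p = 0.0723), and H2-D1 and B2m, the light chain of MHC class I, fell to 991 ± 0.573 and 909 ± 13.5 TPM from 1605 ± 4.56 and 1449 ± 3.44 TPM. That list passed without PBS replicate 2 (adjusted p = 0.0396), without CS1 replicate 2 (0.0461) and with no filter (0.0322), within a range of 0.0322 to 0.449 across camera's alternatives.

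**Figure D1:**
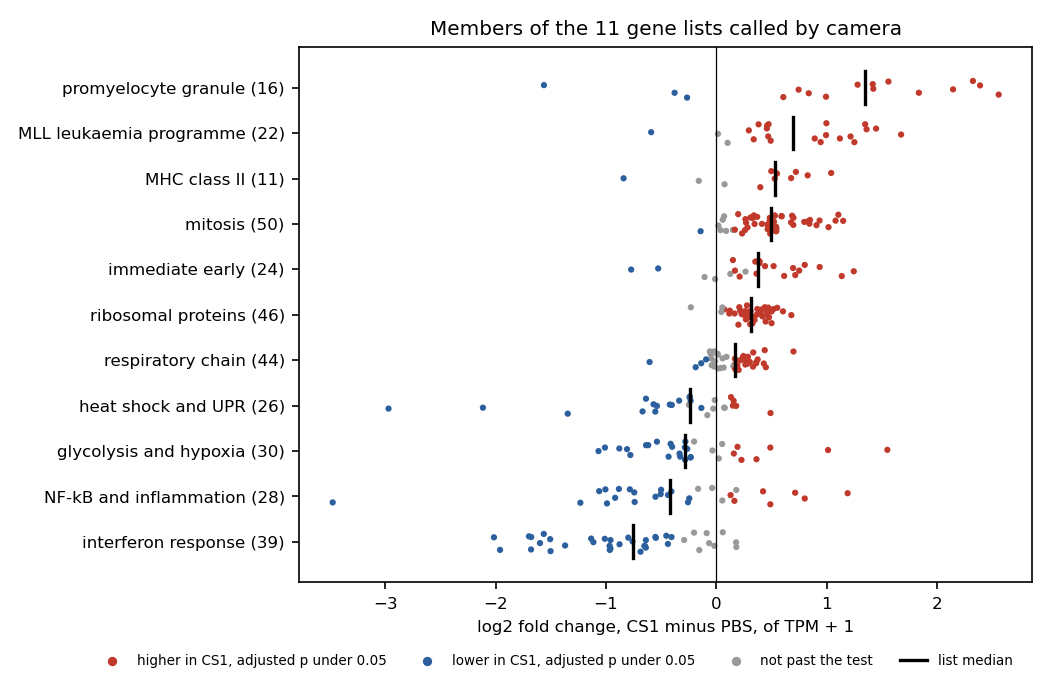
Log2 fold change, CS1 minus PBS on the log2(TPM + 1) scale, of each tested member (point) of the 11 lists called by camera, with the number of members in parentheses and the list median as a black bar. Medians run from 1.35 for promyelocyte granule genes to -0.76 for interferon-response genes, and the vertical spread of points within a list carries no value.

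Interferon-response genes fell in 30 of 39 cases and rose in 0 (median -0.76, camera adjusted p = 9.08e-08, and adjusted p = 0.449 with an estimated correlation). Ifitm3, an antiviral membrane protein, fell from 1709 ± 1.46 to 534 ± 7.04 TPM. The DNA-sensor family member Ifi204 and the nucleic acid sensor Zbp1 had log2 fold changes of -1.68 and -2.01. NF-kB and inflammation genes fell in 17 of 28 cases and rose in 7 (median -0.42, camera adjusted p = 0.0173, and adjusted p = 0.449 with an estimated correlation). Saa3, an acute-phase serum amyloid, fell from 141 ± 2.60 to 11.9 ± 2.38 TPM, and the chemokine genes Ccl9 and Ccl6 had log2 fold changes of -1.06 and -0.92. Complement and efferocytosis genes did not pass, with 3 of 13 higher and 7 lower (median -0.39, adjusted p = 0.114), though C3 and the receptor gene C5ar1 fell by 1.32 and 1.02. Monocyte and macrophage genes did not pass either, with 10 of 24 higher and 13 lower (median -0.35, adjusted p = 0.135). Besides Lyz2, the haem oxygenase gene Hmox1 fell from 276 ± 1.22 to 114 ± 0.651 TPM. Without CS1 replicate 2, both lists passed, at adjusted p = 0.0447 for complement and efferocytosis (range 0.0447 to 0.449 across camera's alternatives) and 0.0433 for monocyte and macrophage genes, whose median then was -0.60 (range 0.0433 to 0.491).

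Heat shock and unfolded protein response genes fell in 15 of 26 cases and rose in 5 (median -0.24, camera adjusted p = 0.0119, and adjusted p = 0.449 with an estimated correlation). The chaperone genes Hspa1a and Hspa1b fell from 201 ± 2.58 and 155 ± 9.0 to 45.6 ± 0.346 and 18.9 ± 1.22 TPM; they are near-identical copies that share reads, so the value of each is uncertain. Edem1, of endoplasmic reticulum quality control, had a log2 fold change of -0.67. Glycolysis and hypoxia genes fell in 19 of 30 cases and rose in 7 (median -0.28, camera adjusted p = 0.0173, and adjusted p = 0.449 with an estimated correlation). The glucose transporter gene Slc2a1 fell from 73.9 ± 0.318 to 36.2 ± 0.580 TPM, and Ndrg1 and P4ha1 had log2 fold changes of -0.78 and -1.07. Both calls were lost after quantile normalization (adjusted p = 0.0843 each), over ranges of 0.00348 to 0.449 for heat shock and 0.00823 to 0.449 for glycolysis across camera's alternatives.

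Fto itself was measured at 30.2 ± 0.969 TPM in PBS and 31.4 ± 0.735 TPM in CS1 and did not pass the test (log2 fold change 0.06 ± 0.05, adjusted p = 0.334). The other m6A demethylase gene, Alkbh5, fell from 47.2 ± 1.15 to 37.3 ± 1.56 TPM. The list of m6A writers, erasers and readers did not pass, with 3 of 19 higher and 9 lower, or 4 and 9 adjusted over the list alone (median -0.08, adjusted p = 0.335), and Ythdf3, an m6A reader, and Hnrnpc fell by 0.58 and 0.30 on the log2 scale. FTO-linked targets did not pass as a list, with 1 of 6 higher and 3 lower (median -0.27, adjusted p = 0.297); since the list may rest partly on these samples, it is not independent evidence. Within it Lilrb4a, an inhibitory immune receptor, fell from 741 ± 6.28 to 419 ± 7.0 TPM (log2 fold change -0.82 ± 0.02, adjusted p = 4.45e-06). Myc fell from 68.3 ± 3.95 to 40.2 ± 2.81 TPM and the retinoic acid receptor gene Rara from 218 ± 4.88 to 141 ± 0.707 TPM. Cebpa stood at 161 ± 5.98 and 170 ± 5.69 TPM and Asb2 at 1.08 ± 0.0778 and 1.25 ± 0.219 TPM in PBS and CS1, neither past the test (adjusted p = 0.112 and 0.538). Cebpa passed after quantile normalization (adjusted p = 0.0182) and with the replicate block (0.0495), within a range of 0.0182 to 0.741 across alternatives. Immune checkpoint genes were higher in 3 of 15 cases and lower in 9 (median -0.45, adjusted p = 0.069). Among them Vsir, which encodes VISTA, fell from 476 ± 2.23 to 282 ± 0.948 TPM and Cd274, which encodes PD-L1, from 12.9 ± 0.403 to 6.18 ± 0.127 TPM. The checkpoint list passed without CS1 replicate 1 (adjusted p = 0.0384) or CS1 replicate 2 (0.0433), within a range of 0.0384 to 0.46 across camera's alternatives.

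**Figure D2:**
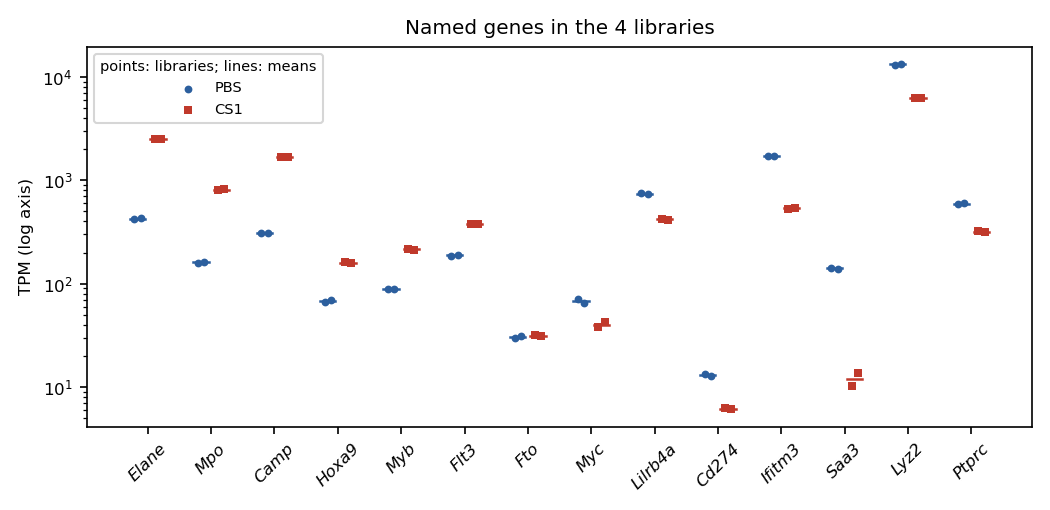
TPM on a log axis of 14 genes in the PBS libraries (circles) and the CS1 libraries (squares), with group means as lines. Fto lies at 30.2 and 31.4 TPM on average and did not pass the test, while Elane is higher in CS1 (425 against 2512 TPM) and Lyz2 lower (13192 against 6207 TPM).

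Among protein-coding genes, the largest rise and the largest fall lay close to each other on chromosome X, with Aifm1 between them. Elf4 (X, 48411046 to 48463132, mm10, minus strand) had a log2 fold change of -4.07 ± 0.04 (SE, adjusted p = 4.63e-07), and Rab33a (X, 48519285 to 48530232, plus strand), a small GTPase gene, rose from 0.50 ± 0.0849 to 35.7 ± 1.68 TPM (4.61 ± 0.10, adjusted p = 2.74e-06). The neighbouring protein-coding genes, the corepressor gene Bcorl1 (X, 48341358 to 48408049) and the mitochondrial flavoprotein gene Aifm1 (X, 48474944 to 48513563), were named for their position after the values were seen. Bcorl1 went from 5.31 ± 0.0283 to 0.80 ± 0.0566 TPM and Aifm1 from 29.5 ± 0.247 to 9.50 ± 1.19 TPM. The nearest tested genes on either side changed less, with log2 fold changes of -0.21 for Utp14a and 0.41 for Zfp280c.

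**Figure D3:**
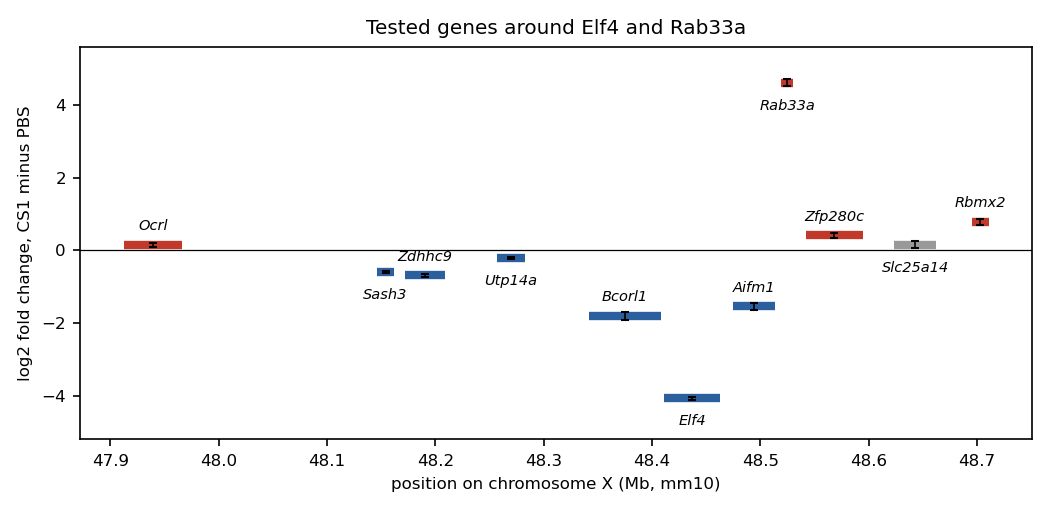
Log2 fold change, CS1 minus PBS on the log2(TPM + 1) scale, of the tested genes around Elf4 on chromosome X, each drawn as a bar over its annotated span in mm10, with the SE as an error bar (red higher, blue lower, grey not past the test). Elf4 (-4.07), Bcorl1 (-1.81) and Aifm1 (-1.54) are lower and Rab33a (4.61) higher, while the flanking genes lie between -0.69 and 0.78.

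Among the other protein-coding genes with the largest falls were Cd300c2 (176 ± 1.12 to 19.4 ± 1.63 TPM), Cd300ld (253 ± 0.0424 to 50.8 ± 0.0141 TPM) and Cd300ld3, which belong to a family of myeloid receptors with similar sequences, so that the value of each is uncertain. Igfbp6 and Ip6k3 had log2 fold changes of -2.23 and -2.13. Among the largest rises were the citrate transporter gene Slc13a5 (0.63 ± 0.127 to 15.7 ± 0.587 TPM), the acute-phase gene Orm1 (2.21 ± 0.0636 to 24.8 ± 1.45 TPM) and Ptgs1, which encodes cyclooxygenase-1 (6.20 ± 0.283 to 46.7 ± 1.42 TPM). Sult1a1, Ppp1r14a, Serpine2, Hif3a and Fhdc1 had log2 fold changes between 2.69 and 2.96. Sept5 rose by 2.81 but shares 1902 bases of exon with Gp1bb, so the values of both genes are uncertain. Before the restriction to protein-coding genes, short noncoding RNAs made up 5 of the 10 largest falls and 7 of the 10 largest rises. Of those 20 features, 11 were listed at 0.01 in a whole group and have no fold. Mir7030, Mir7059, Snord69, Mir7023, Mir7012 and Hbb-b1 were listed at 0.01 in both CS1 libraries, and Mir425, Mir7014, Mir25, Hbb-bs and Hist2h2aa2 in both PBS libraries. Mir7059 and Snord69 had the same values in every library, 13.18 and 13.48 TPM in PBS 1 and PBS 2. Without counts it could not be tested whether such short features rest on few reads. Snord99, Mir7067, Mir7079 and Snord49a, listed at 0.01 in 1 PBS library each, rose to means of 90.2, 41.9, 32.0 and 35.7 TPM. All 4 calls were lost without CS1 replicate 1 (adjusted p = 0.117, 0.0885, 0.0535 and 0.0673), and those of Snord99 and Snord49a without CS1 replicate 2 (0.0666 and 0.0946), within a range of 0.000215 to 0.117 across alternatives. Snord69, Snord99, Mir7014, Mir7079 and Mir25 lie within exons of Gnl3, Snhg12, Ecm1, Rpl13 and Mcm7, so their values are uncertain. As a sign of poly(A) selection, 11 other RNAs without a poly(A) tail had a median log2 fold change of 0.56, with 4 called higher and 1 lower.

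No list of markers of another spleen cell type passed the camera test with all 4 libraries and the main settings, and the median level of the members of such a list reached at most 3.21 TPM, for dendritic cells in CS1. The highest members, averaged over the 4 libraries, ran from Cd2 of the T cell list at 17.7 TPM to Cd37 of the B cell list at 308 TPM, both named outside the rule. Flt3, the highest dendritic cell member at 283 TPM, is also in the MLL leukaemia programme list. Such lists therefore need not track other cell types alone. T cell genes were higher in 1 of 15 cases and lower in 7, or 1 and 6 adjusted over the list alone (median -0.32, adjusted p = 0.154), with Thy1 lower (log2 fold change -1.31) and Cd5 higher (1.00). That list passed after quantile normalization (adjusted p = 0.0478) and with no filter (0.0103), within a range of 0.0103 to 0.46 across camera's alternatives. The cytotoxic and NK list had 3 members higher and 3 lower of 6 (median -0.04 and mean 0.07, adjusted p = 0.845), with Nkg7 at 1.84 and Il2rb at -1.10. With no filter it passed as lower (adjusted p = 0.0165, range 0.0165 to 0.981 across camera's alternatives). B cell genes were higher in 3 of 19 cases and lower in 7 (median -0.18, adjusted p = 0.365), with Cd72 at 1.26 and Cd79b at -0.75; Cd72 overlaps a gene on the opposite strand and is uncertain. Of 5 plasma cell genes 1 was higher and 3 were lower (median -0.34, adjusted p = 0.261), with Jchain at -2.24 and Xbp1 at -0.34. Dendritic cell genes were higher in 7 of 12 cases and lower in 2 (median 0.62, adjusted p = 0.212), with Flt3 and Tcf4 at 1.00 and 0.77. Erythroid genes were higher in 6 of 14 cases and lower in 2 (median 0.19, adjusted p = 0.365), with Fech at 0.64. Megakaryocyte and platelet genes were higher in 7 of 10 cases and lower in 1 (median 0.57, adjusted p = 0.252), with Plek at -0.96 and Gp1bb at 1.78. The mast cell, basophil and eosinophil list had 3 members higher and 2 lower of 7 (median 0.16, adjusted p = 0.807), with the basophil protease gene Mcpt8 at 2.62 and the eosinophil ribonuclease gene Ear2 at -2.05. Stroma and endothelium genes were higher in 3 of 6 cases and lower in 2 (median 0.22, adjusted p = 0.725), with Egfl7 at 1.29 and Pecam1 at -0.26. Ptprc, the gene of CD45 itself, fell from 590 ± 9.74 to 319 ± 6.05 TPM (log2 fold change -0.89, adjusted p = 4.66e-06).

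The remaining lists did not pass either. Lysosome and autophagy genes were higher in 9 of 31 cases and lower in 17 (median -0.21, adjusted p = 0.0505), with Hexa lower (304 ± 0.594 to 152 ± 1.61 TPM) and Psap at -0.77. That list passed without PBS replicate 2 (adjusted p = 0.0457), without CS1 replicate 2 (0.0433), after rescaling by the trimmed mean of M values (0.0466), with no filter (0.0139) and without the short noncoding features (0.0485), within a range of 0.0139 to 0.449 across camera's alternatives. The late neutrophil list passed without CS1 replicate 1 (adjusted p = 0.0352), without CS1 replicate 2 (0.0338), after the same rescaling (0.0279), with a filter of 5 TPM (0.0398) and without the short noncoding features (0.0485), within a range of 0.0279 to 0.449. Targets of p53 were higher in 13 of 29 cases and lower in 8 (median 0.10, adjusted p = 0.365). Pmaip1, which encodes the apoptosis inducer NOXA, and Ddit4 rose by 0.90 and 0.62, while Cdkn1a stood at 75.4 ± 3.76 and 76.3 ± 0.552 TPM (adjusted p = 0.722). Intrinsic apoptosis genes were higher in 5 of 25 cases and lower in 12 (median -0.12, adjusted p = 0.0816), with Bak1 at -0.88, a gene that overlaps another on the opposite strand. With no filter that list passed (adjusted p = 0.0245, range 0.0245 to 0.46 across camera's alternatives). Pyrimidine and purine synthesis genes were higher in 3 of 26 cases and lower in 14 (median -0.14, adjusted p = 0.114), with Impdh1 at 1.36 and Mthfd2 at -1.29. It passed with no filter (adjusted p = 0.0499, range 0.0499 to 0.578 across camera's alternatives). Dhodh, of pyrimidine synthesis, stood at 15.4 ± 0.495 and 17.1 ± 0.523 TPM (adjusted p = 0.0876). Cholesterol synthesis genes were higher in 6 of 24 cases and lower in 10 (median -0.16, adjusted p = 0.264), with Pmvk at 0.93. In total 11 of the 34 lists passed, 7 higher and 4 lower, and for 29 lists the counts adjusted over the list alone equalled those over all tested genes. With an estimated correlation camera called 0 lists, with 1 (mitosis) at an unadjusted p under 0.05, while fry, which tests a list against no change and not against other genes, called 25.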

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

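Leaving out the short noncoding features and the settings tried for the relations between libraries were chosen after the data were seen. The count of changed genes lay between 7116 and 8119 under the scalings, tests, filters, pseudocounts and feature sets tried, between 6679 and 6888 with 1 library left out, where the lone library is assumed to vary like the other group, and at 8732 with an adjusted p under 0.1. Asking also for a log2 fold change of at least 1 left 886 genes, 596 higher and 290 lower. Rescaling by the trimmed mean of M values moved the share of higher calls from 52.8% to 45.6%, and the median log2 fold change from 0.04 to -0.02. With quantile normalization 9 genes were called in the opposite direction. The replicate numbers did not pair the samples (correlation of deviations 0.0219), and the replicate block called 7750 genes, 7604 of them shared with the fit without it, and the same number of lists, 11. Of 113 named genes past the test none reversed where tested. Calls were lost for Snord99, Mir7067, Mir7079 and Snord49a, each in at least 2 settings. Only 102 of the 113 were tested without CS1 replicate 1 or without CS1 replicate 2, since the filter then dropped genes under 1 TPM in PBS. Rab33a, Slc13a5, Hif3a, Fhdc1 and Serpine2 were among those dropped, so their rises were not checked without CS1 replicate 2. Filters dropped some low genes in other settings.

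The number of called lists was 17 with no filter, 0 with an estimated correlation and 25 with fry, and 11 to 17 with 1 library left out, the 17 being without CS1 replicate 2, where the 11 called lists stayed called and 6 were added. With no filter the cytotoxic and NK list was lower, with a median of -0.319, since many members below 1 TPM enter it. The mean correlation within groups exceeded that across groups by 0.0335, and by 0.0153 with no filter, 0.0492 with a filter of 5 TPM, 0.0414 with a pseudocount of 0.1 and 0.0291 with one of 5; the cause was not tested. Depth is unknown, so the counting error of low genes could not be given.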

Other observations

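Tests chosen only after the result was seen were all those on the chromosome X block and on the granule genes, the comparison of histone genes with DNA replication genes, and the choice of the gene families. The tests on poly(A) selection and on histone copies were set before their result was seen.

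Several gene families moved largely one way. They were picked by symbol after the data were seen, so their p-values are not independent evidence. Histone genes rose in 50 of 64 cases and fell in 0 (median log2 fold change 1.13, camera adjusted p = 1.63e-08 over 10 families, and adjusted p = 0.135 with an estimated correlation). Reads of histone copies are shared, so single histone genes are uncertain. Homeobox genes of the Hoxa cluster and their antisense RNAs rose in 9 of 11 cases (median 0.69, adjusted p = 0.00118, and adjusted p = 0.138 with an estimated correlation), from Hoxa3 at 0.16 to Hoxa9 at 1.22. The stefin A protease inhibitors, a cluster of close copies, rose in 5 of 5 cases (median 1.76, adjusted p = 0.00118, and adjusted p = 0.199 with an estimated correlation), with Stfa1 at 635 TPM in PBS and 2149 TPM in CS1.

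Families of myeloid surface receptors were lower. The leukocyte immunoglobulin-like receptors and their Pir relatives fell in 9 of 9 cases (median -0.84, camera adjusted p = 2.37e-05, and adjusted p = 0.135 with an estimated correlation), and Pirb went from 1393 to 703 TPM. Cd300 genes fell in 10 of 11 cases and rose in 1 (median -0.95, adjusted p = 0.000154, and adjusted p = 0.135 with an estimated correlation). Cd300ld4 and Cd300ld5 had the same means, 2.085 TPM in PBS and 0.615 TPM in CS1, and the same log2 fold change, which is the family median. They may not be separate measurements. Ms4a genes fell in 7 of 9 cases and rose in 1, which is Ms4a3 (median -0.69, adjusted p = 0.00478, and adjusted p = 0.159 with an estimated correlation). Schlafen genes fell in 6 of 8 cases (median -0.50, adjusted p = 0.00338, and adjusted p = 0.178 with an estimated correlation), and guanylate-binding protein genes in 4 of 6 with 1 higher (median -1.04, adjusted p = 0.047, and adjusted p = 0.239 with an estimated correlation). Small nucleolar RNAs rose in 29 of 57 cases and fell in 3 (median 0.78, adjusted p = 0.00155, and adjusted p = 0.135 with an estimated correlation). Features with a microRNA symbol did not pass as a family, with 31 of 125 higher and 8 lower (median 0.23, adjusted p = 0.174). They include the microRNA host genes Mir17hg and Mir22hg, both called higher. A separate set of 11 RNAs without a poly(A) tail had a median of 0.56.

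On chromosome X, the adjacent genes Bcorl1, Elf4, Aifm1 and Rab33a each changed by at least 1.54 on the log2 scale. Chance placement of large changes is argued against by a scan of all runs of 2 to 6 adjacent tested genes for the highest mean absolute change, which found this region at each length (permutation p = 0.00020 over the lengths, from 10000 random gene orders that treat neighbours as independent; 0.059 for runs of 2 alone). Reads shared between annotated exons are argued against by 0 bases of GENCODE M21 exon common to the 4 genes. The annotation behind the deposited values is not given, and transcripts outside GENCODE M21 were not examined. A single change in copy number is argued against by Rab33a at 4.61 against Elf4 at -4.07. Different leukaemia clones in the 2 groups cannot be told apart from the treatment, because the labels name no clones; the libraries of a group differed by at most 0.0474 in Elf4. A clonal event in this region, such as an insertion or rearrangement, and an effect of CS1 both remain open.

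Of 16 promyelocyte granule genes 13 rose and 3 fell, a list call lost with an estimated correlation (adjusted p = 0.449), and Camp, Ngp and S100a8 rose too. Bead enrichment for CD45.2 selects against recipient neutrophils but can leave some, and it does not remove those derived from donor cells. Admixed maturing neutrophils stay open as a source, because late neutrophil genes went both ways (19 of 31 higher, 10 lower). Their median lay 0.86 below the granule median, less than the SD of 1.08 over the list. A lower share of monocytic cells also stays open, because lists of other cell types rest on low genes and ran from a median of -0.34 for plasma cells to 0.62 for dendritic cells, the latter 0.727761 below the granule median and within its SD of 0.831. Different clones in the 2 groups cannot be told apart from the treatment, with Elane differing by at most 0.0246 within a group. An effect of CS1 on the leukaemic cells was not tested apart from these and stays open.

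Histone transcripts mostly lack a poly(A) tail. Weaker poly(A) selection in the CS1 libraries could contribute, since 11 other RNAs without a tail had a median log2 fold change of 0.56134, with 4 of them called higher and 1 lower. The histone median lay 1.08003 above that of the DNA replication list, whose members had an SD of 0.279. This argues against a rise of equal size in both sets. It cannot decide on more cells in S phase, because it was not shown that both sets would rise alike. That source stays open. Reads split between histone copies are argued against, because the summed histone TPM rose from 767 and 805 in PBS to 1808 and 1898 in CS1, a log2 ratio of 1.23741. An effect of CS1 on histone transcripts is not excluded, and no biological explanation was tested further.

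Globin genes have near-identical copies, and most were listed at 0.01 TPM in some libraries. In PBS 1, PBS 2, CS1 1 and CS1 2, Hba-a1 was listed at 16.2, 17.1, 26.1 and 0.01 TPM, and Hba-a2 at 0.01, 0.01, 0.01 and 19.3 TPM. Hbb-b1 was listed at 9.37, 8.86, 0.01 and 0.01 TPM, and Hbb-bs at 0.01, 0.01, 13.5 and 12.2 TPM. The only other run of 4 adjacent tested genes with changes as large held the olfactory receptor genes Olfr1029, Olfr1030, Olfr1033 and Olfr1034 (2, 85973895 to 86050742), related copies that were all higher in CS1, with Olfr1029 at 3.59 TPM in PBS and 16.2 TPM in CS1.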
